A study of Arabidopsis thaliana with 8 samples.

How the data were processed

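The series measured dimethylation of lysine 4 of histone H3 (H3K4me2), a nucleosome mark of genes in open chromatin, by chromatin immunoprecipitation on a chromosome 4 tiling array (ChIP-chip). Whole seedlings of a hybrid of the Arabidopsis thaliana accessions Col-0 and C24 were grown for 10 days in liquid medium. The sources of all 8 samples are named ColxC24 and the strain field gives C24, so the hybrid was taken from the source names. The tag for input DNA stands on the Cy5 channel of all 8 samples, including those whose Cy5 source is named IP. The source names were followed, and the antibody is given for the channel they name IP. Each of 4 replicates, numbered I to IV in the labels, was hybridised on 2 arrays as a dye swap: immunoprecipitated DNA (IP) in Cy5 against input DNA in Cy3, and the reverse. No other strain, antibody or treatment was among the samples analysed here, so the comparison was of IP with input. Nothing in the labels says that the replicates came from separate plants or chromatin, and p-values therefore measure only the spread between these 4 samples, which may be technical.

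The only file was the series' table of processed values, with 21800 probe IDs and 8 columns. The values deposited by the authors are log ratios of the 2 channels, taken here as log2. The scanner signals were not used here. How the authors corrected background and normalized, the base of the logarithm and the direction of the ratio are not given in the sources used here. The 2 columns of each dye swap differed at 0 probes, so the deposited values belong to the dye swap and not to the array. They were counted as 1 replicate each, n = 4. All 4941 values within 0.1 of 0 carried floating-point residues that fit a subtraction of numbers between 4 and 16, and 90.3% of them fit terms between 8 and 16. A log10 signal of that size would exceed a 16-bit scanner. A natural logarithm was not excluded, and every log2 value below would then be in natural log units. Because the 2 orientations carry the same numbers, the dyes could not settle the direction either. "Above" and "below" refer to the sign as deposited, and with the sign turned every count above and below changes places. The columns were not centred: their medians were -0.69, -0.23, -0.76 and -0.33 in replicates I to IV.

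Of the 21800 IDs, 21295 had a value in every column and 505 had none in any. The latter included all 39 IDs that do not name a plate and well, such as control names. The other IDs read as plate and well of 96-well plates (TA37C01 is plate TA37, row C, well 01). They carry no gene or position. Of the IDs with values, 0 occur in the gene table used for the species (assembly TAIR10.1), so no probe was paired with a gene or a coordinate. For that reason the gene lists, gene and transposon classes and chromosome windows fixed before the data were examined were not tested as planned.

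Each replicate was centred on its median without loess or quantile normalization, since most probes of a ChIP array can carry signal. Ratios were tested against 0, the median probe, with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, 4 replicates, two-sided, Benjamini-Hochberg adjustment over 21295 probes, threshold 0.05). A second test (limma's treat) asked for a size over 0.5. A mixture of 2 normal components was fitted to the mean ratio. A probe was assigned to the upper component at a posterior over 0.5, and always when it lay above that component's mean. The 3 ways of splitting 4 replicates into pairs were each tested with limma. The rule for named probes, fixed with these designs, was the 2 highest and the 2 lowest past 0.05 with 1 sign in all 4 replicates. For the difference between replicate sets the rule was the 3 largest of each sign past 0.05, and it was used for the split that had calls. Plates, ID series and stretches of neighbouring IDs were described after the data were seen. Calculations outside R used Python 3.11.15, numpy 2.4.6 and pandas 2.3.3.

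The limma fits were tested on simulated data with the real probes' spreads, independent replicates and 200 changed probes per size. Against the median, the fit recovered 43.5% of probes shifted by 0.5, 86.5% of those shifted by 1 and 97.0% of those shifted by 2, and unchanged probes made up 5.81% of its calls. These shares leave out the likeness of replicates I with III and II with IV. In a simulation added after the data were seen, with a correlation of 0.730 within these pairs, as estimated from the data, the same fit called 2.17% of the unchanged probes, against 0.135% with independent replicates, and they made up 48.8% of its 922 calls. The p-values are therefore too small if the pairs are not independent samples. Both simulations gave far fewer calls than the data, so the Benjamini-Hochberg cut lay at smaller p-values in them. Their shares of unchanged probes called are no estimate of the false calls in the data. For a split of 2 replicates against 2, the noise was taken only from the spread within I and III and within II and IV. The shares recovered were 19.0%, 66.5% and 93.0%, with 3.51% unchanged probes among the calls. They apply to the split of I and III against II and IV. For the splits that cross these pairs, where the pair difference enters the residual, the recovery was not simulated. The number of arrays limits the precision, and no counts or depths underlie these values. Alternatives were no centring, centring on the mode, quantile normalization, stricter thresholds, the set of title numbers as a term, each replicate left out, and other mixture settings. Averaging replicates I with III and II with IV, treating these pairs as random blocks, moving 0 by the same amount in all replicates, the pairs as a fixed block in the splits that cross them, and other settings for the splits that follow no label were added after the data were seen. The planned test of a dye effect, the fits to 1 dye orientation and the fit of all 8 arrays could not be made, because both orientations hold the same values. The alternative set of probes with values on some replicates did not exist, since 0 probes had a value on some arrays only.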

Results

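The H3K4me2 profile of hybrid Col-0 and C24 seedlings was read on 21295 chromosome 4 probes in 4 replicates, each the combined result of a dye swap of IP against input. The deposited log ratios ran from -5.96 to 3.98 in replicate I, from -5.66 to 4.73 in replicate II, from -5.85 to 3.70 in replicate III and from -5.67 to 4.90 in replicate IV. The spread over probes was alike in the 4 replicates, with SDs of 1.41, 1.32, 1.39 and 1.34. The share of probes above 0 was not: it was 30.9% in I, 28.5% in III, 43.5% in II and 40.8% in IV. All values below are relative to the median probe of each replicate, on a scale taken as log2, with the sign as deposited. After centring, the SD of a probe over the 4 replicates had a median of 0.20, against an SD of 1.34 for the mean ratio over probes (5th percentile -2.73, 95th percentile 1.66).

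The comparison of IP with input asked where on the tiled chromosome the ratio departs from that of the median probe. A large part of the probes did so, on each side. In limma's test, 8956 probes lay above the median and 8999 below it at an adjusted p under 0.05. Of these, 8861 and 8922 had 1 sign in all 4 replicates. The test takes the 4 replicates as independent. In simulated data with replicates alike in pairs it called 2.17% of unchanged probes, against 0.135% without the pairing. Few probes were changed there, so the Benjamini-Hochberg cut lay at smaller p-values than here. These shares are no estimate of the false calls here, where a larger share of unchanged probes would pass the looser cut. Where a distance over 0.5 was required (limma's treat), 5975 probes lay above and 6510 below, and at a distance over 1 the counts were 2723 and 4327. The lower side thus reached further: probes more than 1 below the median outnumbered those more than 1 above it. Against an uncentred 0, the split was 5048 above and 11103 below, and against the mode of each replicate it was 3030 above and 12380 below. With a distance over 0.5, these splits were 2268 to 8371 and 962 to 9614. They also change the spread between replicates. With 0 moved by the same amount in all replicates, to the mean deposited 0 or the mean mode, the splits were 5779 to 11885 and 4197 to 13474, so the balance of the 2 sides depends on where 0 is placed. Probes called above the median turned to calls below in these placements, 202 with 0 at the mean deposited 0, 1319 with 0 at the mean mode and 275 with each replicate centred on its mode.

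**Figure D1:**
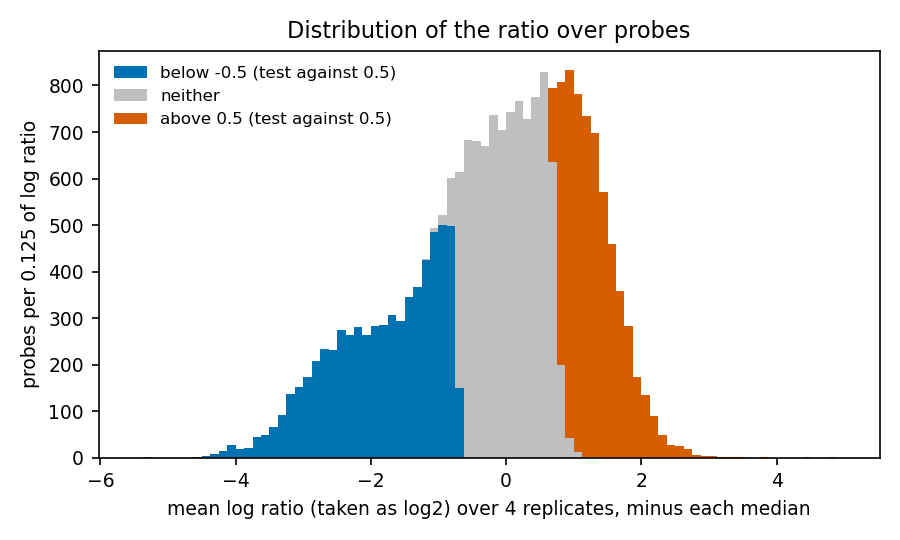
Histogram of the mean log ratio over 4 replicates (horizontal axis, taken as log2, centred on each replicate's median) with the number of probes per bin on the vertical axis. Colours mark the 6510 probes below and the 5975 above in the test against a distance of 0.5, and the lower side has a shoulder between about -3 and -2 that the upper side lacks.

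A mixture of 2 normal components placed the upper one at a mean of 0.72 with an SD of 0.72, and the lower one at -1.02 with a larger SD of 1.24. The fitted weight of the upper component was 48.5% (46.1% to 50.3% in single replicates), and 54.3% of the probes of the mean profile were assigned to it. With the sign turned, the component that is then the upper one held 45.7%. In single replicates, with the sign as deposited, the share assigned was 51.8% in I, 54.3% in II, 55.7% in III and 52.7% in IV, a mean of 53.6% ± 1.73 (SD, n = 4). The components overlapped widely. With the posterior bound at 0.9, 29.5% were assigned to the upper component, all of them as probes above its mean. The fitted posterior stays below 0.9, so no probe passed that bound itself. A common variance placed 77.5% in the upper component. The share thus depends on these settings.

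The 4 probes named by rule were far from the median in every replicate. TA94E02 was the highest, at 4.82 ± 0.36 (SD, n = 4; limma adjusted p = 5.3e-07), and TB65A08 followed at 4.47 ± 0.20 (adjusted p = 5.2e-07). Their direct neighbours by ID were also above the median but much lower, at 1.37 and 2.04 beside TA94E02 and at 1.48 and 0.16 beside TB65A08. The lowest probe, TA37C01, was at -5.27 ± 0.17 (adjusted p = 5.2e-07), between neighbours at -1.79 and -2.81. TA41B04 was at -4.57 ± 0.49 (adjusted p = 1.1e-06), between neighbours at -4.29 and -2.48. The genes under these probes were not identified here.

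The ratio differed between the ID series. The 9458 probes of the TB plates had a median of 0.47 ± 0.02 (mean of 4 replicate medians, SD, n = 4), with 3670 of them (38.8%) above and 1320 below in the test against 0.5. The 1268 probes of plates TC00 to TC13 were within the spread of that, at 0.42 ± 0.09, with 34.2% above and 14.7% below. The 9057 probes of the TA plates were lower, at -0.50 ± 0.05, with 19.2% above and 43.1% below. The 1102 probes of plates TC17 to TC30 were lowest, at -2.14 ± 0.15, with 14 probes above and 994, or 90.2%, below. Their median minus that of the TB plates was -2.60 ± 0.17 (SD, n = 4), in the same direction in 4 of 4 replicates. An exact two-sided sign-flip test on 4 replicates cannot go below p = 0.125. The 315 probes of the PD plates were near the median, at -0.11 ± 0.06, and the 95 probes of plate TD01 were at 0.69 ± 0.05. Without centring the medians of the TB plates and of plates TC00 to TC13 were -0.04 and -0.09, and centred on the mode that of plate TD01 was -0.07, so the sign of these medians depends on the choice of 0.

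Low probes were gathered in long stretches of plates. Of 231 plates, 43 had a median under -1 in all 4 replicates, and 0 of the 100 TB plates were among them. The longest stretch was TA37 to TA51, 15 plates with 1342 probes, at a median of -2.10 ± 0.16 (SD, n = 4), where 1195 probes (89.0%) lay below and 15 above. The 10 plates TA21 to TA30 held 823 probes at -1.99 ± 0.11, with 77.2% below and 6.68% above. TC17 to TC25 held 784 probes at -2.23 ± 0.14, with 93.5% below, and TC27 to TC30 held 318 at -1.82 ± 0.22, with 82.1% below. The remaining low plates were TA53, TA57, TA59 and the pair TA62 and TA63, with medians between -1.80 and -1.08. At the other end, plates TB80, TB54 and TB45 had the highest medians, 1.06 ± 0.09, 1.05 ± 0.02 and 1.03 ± 0.15, and 69.8% of the probes of TB80 lay above. Plates above the median in all 4 replicates numbered 118, 80 of them TB plates. The bound of -1 was chosen after the data were seen.

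**Figure D2:**
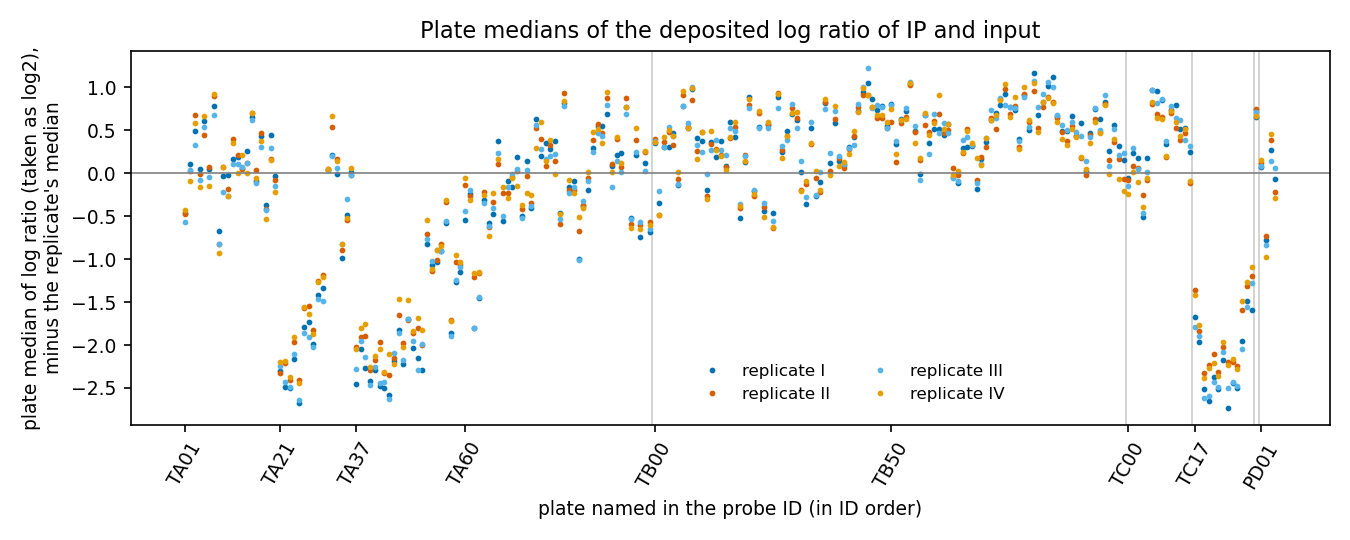
Median log ratio of each plate (vertical axis, taken as log2, centred on each replicate's median) against the plate in ID order (horizontal axis), with 1 point per replicate and grey lines between ID series. TA21 to TA30, TA37 to TA51 and TC17 to TC30 lie below -1 in the 4 replicates, while no TB plate does.

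Probes with neighbouring IDs had similar ratios. Over all pairs of wells 1 apart, the Pearson correlation across probes was 0.75, and it was 0.62 at 2 wells, 0.50 at 5, 0.44 at 10 and 0.34 at 96 (probes are not independent replicates, so no p is given). In the TB plates, which have no long low stretch, it fell faster, from 0.59 at 1 well to 0.36 at 2, 0.17 at 5 and 0.06 at 20. In the TA plates it was 0.73 at 1 well and still 0.33 at 20. Probes above in the test against 0.5 formed 2419 runs of consecutive IDs, with a mean length of 2.47 probes against 1.38 in 100 shuffles of the calls. The longest, TB07H01 to TB08A10, had 22 probes at a mean of 1.45 ± 0.06 (SD, n = 4). TA36B01 to TA36C08 followed with 20 probes at 1.35 ± 0.10, although it lies just before the low stretch that begins at TA37. Probes below formed fewer and longer runs, 1913 with a mean of 3.40, and 58.8% of them were in runs of 5 or more, against 33.8% of the probes above. The longest low run, TA43A08 to TA44B03, had 104 consecutive probes at -2.37 ± 0.10, and TC27A04 to TC28A01 had 94 at -2.33 ± 0.12. The longest run in the shuffles had 11 probes above and 12 below.

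The replicates agreed closely in their profile, and in pairs. Over 21295 probes the Pearson correlation was 0.99 between I and III and 0.99 between II and IV. It was 0.95 between I and II and between II and III, and 0.94 between I and IV and between III and IV. The SD of the centred difference was 0.22 for I and III and for II and IV, and 0.44 to 0.46 for the other pairs. The titles of I and II share 1 set of numbers and those of III and IV another, a possible batch, so the replicates were also compared along these sets. In limma's test of I and II against III and IV, 0 probes passed an adjusted p of 0.05 and 28 an unadjusted p of 0.05, where chance gives about 1065, and 5 to 10 passed the adjusted p with any 1 replicate left out. This split crosses the like pairs, whose difference entered its residual, so the 0 is no evidence against a batch. With I and III and II and IV as a block, 9 probes passed the adjusted p and 1629 the unadjusted. The other possible splits follow no label, and their computation was fixed before the data were examined. For I and IV against II and III, which crosses the pairs as well, the count was 0 (34 unadjusted), 5 to 10 with any 1 replicate left out, and 0 with the block (747 unadjusted). The split of I and III against II and IV called 8147 probes, 38.3% of those tested: 4501 were higher in II and IV and 3646 lower. Without replicate I the counts were 2708 and 1957, and without replicate III 2612 and 1963. Uncentred, where the medians of II and IV exceed those of I and III, they were 13311 and 480, and after quantile normalization 3736 and 4032, so which side is the larger depends on the scaling.

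**Figure D3:**
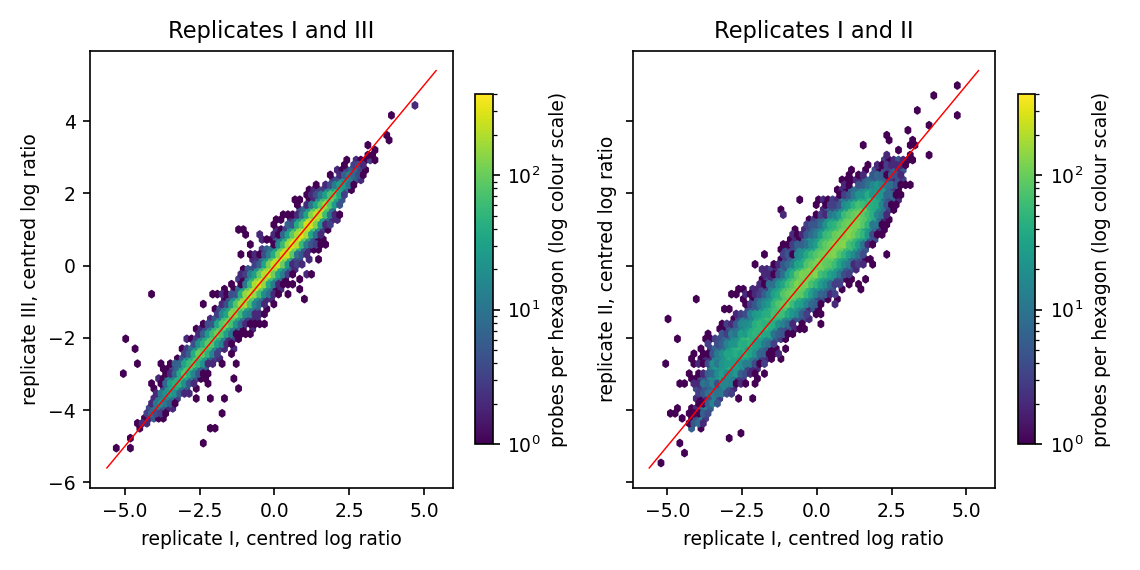
Centred log ratio of replicate III (left) and of replicate II (right) against that of replicate I, with colour giving the number of probes per hexagon on a log scale and the red line marking equal values. Points lie closer to the line for I and III (r = 0.99) than for I and II (r = 0.95).

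The probes that separated I and III from II and IV did so by a median of 0.54 among the calls, and 510 calls exceeded 1. The SEs and p-values of this split rest on the spread within the pairs. If each pair is 1 preparation measured again, they leave out the spread between preparations. TA84E03 had -1.74 and -1.65 in I and III against 0.32 and 0.70 in II and IV, a difference of 2.21 with an SE of 0.14 (limma adjusted p = 0.0012). TB68G12 differed by 2.03 with an SE of 0.37 (adjusted p = 0.0070), and its replicates were less alike, at -1.11 and 0.23 in I and III. TA85F04 differed by 2.02 with an SE of 0.16 (adjusted p = 0.0014). TC10B10, TB35B05 and TB38F01 were lower in II and IV, with differences of -2.01 (SE 0.12), -1.99 (SE 0.11) and -1.93 (SE 0.10). TC10B10 had 1.52 and 1.46 in I and III against -0.66 and -0.37 in II and IV. In 1039 of the called probes the pairs lay on opposite sides of the median. Plates TC17 to TC30 had 34.2% of their probes higher in II and IV and 4.81% lower, while plates TC00 to TC13 had 11.8% higher and 26.7% lower. These series were the most opposed. The TA plates had 23.7% higher and 14.7% lower, the TB plates 18.4% and 19.6%, and the PD plates 21.9% and 18.4%. Over probes the difference correlated with the mean ratio at -0.156, and the shares per series were not computed after quantile normalization. The difference was correlated between direct neighbours, with a Pearson correlation of 0.365 across probes 1 well apart, against 0.128 for the split of I and II against III and IV and 0.089 for that of I and IV against II and III.

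**Figure D4:**
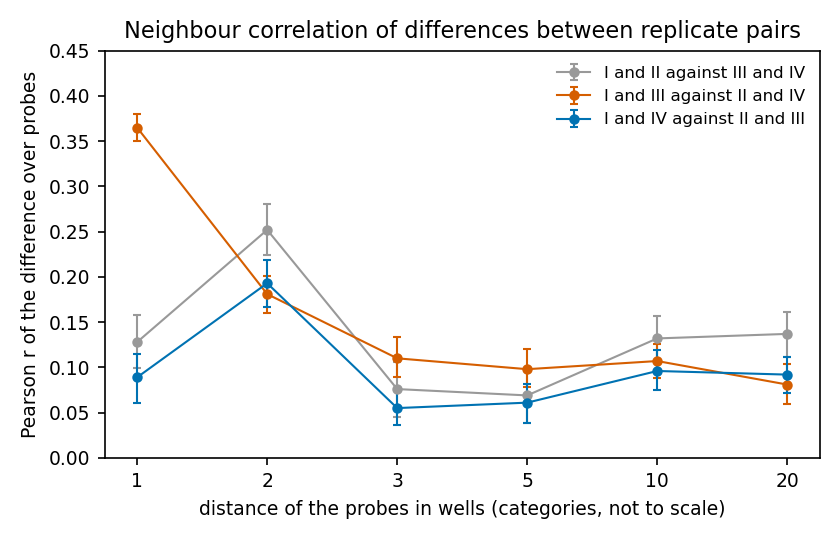
Pearson correlation, across pairs of probes, of the difference between replicate pairs (vertical axis) against the distance of the probes in wells (horizontal axis, categories not to scale), with 95% bootstrap intervals over plates for the 3 splits. At 1 well the split of I and III against II and IV (0.365) lies above the others (0.128 and 0.089), and at 2 wells it does not (0.181 against 0.252 and 0.193). Each correlation is relative to the spread of its own split (SD of the difference over probes 0.426 against 0.158 and 0.147). In TC17 to TC30 the units resampled were blocks of wells offset from the real plates.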

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

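Tests with I and III, and II and IV, averaged or as blocks, those with 0 moved alone, other settings of the split of I and III against II and IV, and all tests of the ID series were chosen after the result was seen. Without centring, 5048 probes lay above 0, and 2268 in the test against 0.5, and centred on the mode, 0.34 to 1.15 above the median, 3030 and 962. Both settings also raised the median SE, from 0.10 to 0.15 and 0.22, and the mode fit gave all probes 1 pooled SE. With 0 moved alone, by the mean of these shifts, 5779 and 2898 lay above for the first and 4197 and 1636 for the second, where 10608 lay below against 0.5; place of 0 and spread thus each lowered the counts above. A threshold of 1 in place of 0.5 left 2723 above and 4327 below. Quantile normalization, the set of title numbers as a term, an adjusted p of 0.01 and leaving out each replicate kept the 4 counts within 1.5 times. As random blocks, the pairs I and III and II and IV gave 8243 above and 8303 below, with a median SE of 0.16. Averaged to 2 values they gave 8047 and 8109, but with 1 SE of 0.21 pooled over all probes, so that a call rests on the mean alone and says little on the effect of the pairing. The upper mixture component held 29.5% with the posterior bound at 0.9, all of them only as probes above its mean, and 77.5% with a common variance. The split of I and II against III and IV called 0 probes, 9 with the pairs I and III and II and IV as a block, which takes their difference out of the residual, and 5 to 10 with 1 replicate left out, so that 1 sample stood for a pair and was assumed to vary like the other; the split of I and III against II and IV called 8147. For the latter, 13311 were higher and 480 lower in II and IV without centring, and with 1 replicate left out 2612 to 3768 and 1957 to 2908, with losses over 1.5 times only without I (2708 and 1957) or III (2612 and 1963). The mean correlation of the 6 pairs was 0.960 by Pearson and 0.954 by Spearman. The 4 named probes kept their sign and side of the threshold in 48 of 48 alternatives. They had been chosen as the most extreme, so this says little on the robustness of other calls. Medians of the ID series moved by less than their SD in 31 of 48 cases. The cases with 1 replicate left out could not move by more, whatever the data, and say nothing on robustness. Without centring and centred on the mode, the median of every ID series moved by more than its SD. Apart from the values given, the cause was not tested. Not run were the alternatives of 1 dye orientation, of all 8 arrays with a dye term and of partly measured probes, and those for the dye effect, gene lists, chromosome regions and gene or transposon tiles. Without scanner signals, no limit from signal over background was set.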

Other observations

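The splits of the replicates, quantile normalization and the chromosome windows had been fixed before the data were examined; the tests made with them here, and the tests on neighbouring wells and plates, were chosen after the pattern had been seen. Those windows were 1.6 to 2.4 Mb for the heterochromatic knob of the short arm and 2.8 to 5.2 Mb for the centromere and pericentromere. As the probes have no coordinates here, the windows were laid on plates TA01 to TC13 as if these followed chromosome 4 from end to end at even spacing. The knob window then fell on TA19 to TA28, with a median of -1.90 ± 0.11 (SD, n = 4), and the pericentromere window on TA33 to TA60, with -1.60 ± 0.10. The stretch between them was at -0.58 ± 0.10, the short-arm end at 0.13 ± 0.03 and the long arm at 0.34 ± 0.01.

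In the mean profile, the median inside these windows minus that outside was -1.996. In replicates I to IV this difference was -2.09, -1.88, -2.05 and -1.84 (SD 0.120), lower inside in 4 of 4. Among 426 placements of the windows, shifted by whole plates and read in either direction, 4 were as low: the one above and its shifts by 1 to 3 plates, which were slightly lower (to -2.02) and overlap it. H3K4me2 is known to be scarce in heterochromatin. The low stretches TA21 to TA30 and TA37 to TA51 would thus go with IDs TA01 to TC13 in chromosome order and a ratio of IP over input. Plates TC17 to TC30, the lowest ID series and 13 of the 43 low plates, were not covered. TA62 and TA63 fell in the long-arm window, and the low plates TA29 and TA30 between the 2 windows. Plates TA20, TA35 and TA36 lay inside the windows with medians of only -0.12, -0.46 and 0.005. Whether each plate has a level independent of the others, from amplification or printing, was not decided. Direct neighbours correlated at 0.701 across plate borders (95% bootstrap interval 0.591 to 0.790, 215 pairs). Within plates they correlated at 0.747, which lies inside that interval. These pairs cover all plates. In TC17 to TC30, however, the borders used were offset and lay inside the real plates. Probes 96 wells apart, which lie in different plates, correlated at 0.335 (95% bootstrap interval 0.273 to 0.390). This value restates the runs of low plates and the differences between ID series that prompted the test. It was 0.252 in the TA plates, 0.017 in the TB plates, 0.069 in TC00 to TC13 and 0.096 in TC17 to TC30. The drop in covariance across plate borders around the low plates was 0.0050 (-0.280 to 0.321). It did not decide either, set against the extra variance of plate means there, 0.352 (0.181 to 0.505). Both values used the offset borders in TC17 to TC30, so part of the pairs and plates behind them were not the real ones. A level shared by a block of neighbouring plates cannot be told apart from chromosome order. The step between medians over rows A to D and rows E to H was taken in the low plates and those next to them. It was 0.139 larger across plate borders than within plates (-0.006 to 0.273), and within plates 0.064 larger than in TB plates (-0.072 to 0.204). In TC17 to TC30, 13 of the 43 low plates, the same offset moved these blocks of rows off the real ones. The steps therefore mix both kinds there and cannot decide.

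Replicate I resembled III, and II resembled IV, more than replicates with the same set of title numbers resembled each other. Independent noise of single spots is argued against as the whole cause, since the difference between these pairs correlated at 0.365 between neighbouring probes (95% bootstrap interval 0.350 to 0.380). A printing effect shared by neighbouring wells stays open. At 2 wells the correlation (0.181) was not above that of the other splits (0.252 and 0.193). Each correlation is relative to the spread of its own split, however, an SD over probes of 0.426 against 0.158 and 0.147. Level-dependent scaling is argued against as the whole cause, since the split called 7768 probes after quantile normalization and 8147 without it. A part of it stays open. Before this normalization the difference correlated with the mean ratio at -0.156 over probes, and the normalization changed which side was the larger. Plant material or chromatin shared within the pairs cannot be told apart from other sources, because the labels of 0 of the 8 samples name a preparation; the SD of this difference over probes was 2.70 times that of the split along the title numbers. The samples form 1 group, so no biological explanation was tested, and if the pairs are repeats of a preparation the number of independent ones may be 2 and not 4.

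In the other splits the differences correlated more strongly at 2 wells (0.252 for I and II against III and IV, 0.193 for I and IV against II and III) than at 1 well (0.128 and 0.089) or at 3 (0.076 and 0.055).

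The 50 highest probes had a median of 2.73, and the means of their direct neighbours had a median of 1.05 (quartiles 0.37 and 1.54). The 50 lowest probes had a median of -4.15, with neighbours at -2.49 (quartiles -3.42 and -1.29). The SD over the 4 replicates had a median of 0.18 in the former and 0.23 in the latter. Repeated sequence under the low probes was not tested. Wells without an ID made up 6.71% of the 43 plates with a median under -1 in all replicates and 0.765% of the other 188.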
